A study of Mus musculus with 21 samples.

How the data were processed

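Messenger RNA of 21 mouse mammary samples was measured by sequencing of poly(A)-selected libraries with single reads of 100 cycles, per the labels' protocols: 14 MYC-NeuNT tumors, 4 NeuNT tumors and 3 normal glands, grouped by the sample titles. The authors deposited a whole-number read count for each of 36141 RefSeq transcripts per sample, as the file columns show. The authors also deposited an FPKM value per transcript (reads scaled to transcript length and to the mapped reads of the library), per the file headers. The submitters' processing notes name CASAVA 1.8.2, Bowtie 1.0.0, DESeq2 and the mm9 genome, without the role of each. The counting tool, annotation release, strand setting and treatment of reads with several matches are not given in the sources used here. Coordinates are those of the deposited files in mm9, and the reference genome at hand, of another build, was not used for them.

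Transcripts of a gene each hold the reads they share, so each of 24478 gene symbols was represented by its transcript with the highest mean count. More than 1 transcript was listed for 6148 symbols. Totals over these transcripts, given per group in the results, were 10928880 to 15280103 counts. At this depth a floor of 3 counts over the 3 normal glands corresponds to 0.0706 CPM. Of these symbols 56 lay on more than 1 chromosome name. Libraries were checked for duplicates by a chi-square test of their counts, and the closest pair of a group gave 55.97 per degree of freedom, far from identical. No column of sample values was left unused.

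Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, filterByExpr, robust dispersion) on the libraries of the groups compared, in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Adjusted p values of genes in the results come from this test unless another is named. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The 33 gene lists with 500 entries, the named-gene rule, the tests and all alternatives except those named as added were fixed before the data were examined. Lists with at least 3 tested members entered a test. CPM values use TMM library sizes, log2 CPM a prior count of 2, and list scores average members with a mean of at least 1 CPM. Distances, list spreads and correlations were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with exact enumeration of all splits or 100000 resamples, all two-sided. Figures were drawn with matplotlib 3.10.9.

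Named genes were 12 fixed in advance, and for each comparison the 6 highest and 6 lowest log2 differences among genes past the test. The latter needed a mean of at least 10 CPM in the higher group and every library of the smaller group on one side of the larger group's median. For each list past its test, the 2 members with the smallest p in its direction were added, and for the spread among MYC-NeuNT tumors the 12 genes of highest variance. Predicted genes were passed over, and some genes that the rule names are not reported here. Genes named beyond this rule, such as members that moved against their list and further members of a list, were chosen after their values were seen.

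The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma voom with group variances, no filter on low counts, all 21 libraries in 1 fit, milk protein genes left out, limma on log2 FPKM with pseudocounts of 1 and 0.1 (mean FPKM of at least 1), a test against a fold change of 1.5, the sample number as a block, and each library left out. For lists the estimated correlation, fry, other size factors and the block were tried, for distances 500 genes, all genes, Euclidean distance, other size factors, FPKM and no lists of non-tumor cells, and for spreads and correlations median scores, other size factors and, for correlations, FPKM. Added after the data were seen were fits without the tumors that held muscle or lymphoid markers, with the transcript of median count, and with the lowest share of NeuNT tumor 1 subtracted from normal glands. Stretches of neighbouring genes were searched in windows of 25 genes among 10865 genes with a mean of at least 10 CPM, against 1000 shuffles of the gene order. The interval around Erbb2 was searched over 1 Mb to each side with 10000 shuffles, among genes with a MYC-NeuNT median of at least 4 CPM, first without Erbb2 itself and then with it.

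The gene tests were checked on simulated data with 50 genes at each of 4 fold sizes, and the run test around Erbb2 was not checked by simulation. Between tumor genotypes (14476 genes) edgeR recovered 28%, 58%, 82% and 80% of genes changed 2, 4, 8 and 16-fold, with 3 false calls. For MYC-NeuNT tumors against normal glands (15068 genes) the shares were 6%, 52%, 82% and 82%, with 9 false calls. For NeuNT tumors against normal glands (14425 genes) they were 0%, 36%, 76% and 84%, with 6 false calls. DESeq2 made 45, 87 and 65 false calls in the same simulations and recovered 154, 135 and 141 of 200 planted genes. A planted list was recovered in each comparison and 0 of 20 unchanged lists were called, by camera. The window search called a block in 1 of 100 simulated libraries without one and found 19 of 19 planted blocks, with edges up to 17 genes off. Values there were drawn independently for each gene, with 200 shuffles and planted blocks of 35 genes. Neighbours expressed together were absent, so these rates may not carry over to the real search.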

Results

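Messenger RNA was sequenced from 21 pieces of mouse mammary tissue in 3 groups. The 14 MYC-NeuNT tumors came from mice in which Blg-Cre, a recombinase driven by the beta-lactoglobulin promoter in mammary epithelium, switched on both a MYC allele in the Rosa26 locus and NeuNT, an activated form of the receptor ERBB2. The 4 NeuNT tumors carried activated NeuNT without MYC, and the 3 normal glands came from mice with the MYC allele but no Cre. Tumors were collected at a diameter of 20 mm, and they arose 4 to 12 weeks after Cre activation with MYC and NeuNT together and after 28 to 44 weeks with NeuNT alone. Genotype therefore goes with time to tumor, and the effects of the 2 cannot be separated in these samples. The tumor-bearing genotypes were bred from 8 weeks of age through 2 cycles of pregnancy. The labels do not give the parity or stage of the normal glands, so whether reproductive history differed between them and the tumors is not known. The deposited counts of 1 transcript per gene summed to 11480332 to 13721908 in MYC-NeuNT tumors, 10928880 to 12305712 in NeuNT tumors and 12426286 to 15280103 in normal glands. Between 16161 and 17761 genes had a count in a library, and the 10 most abundant genes took 4.18% to 13.2% of the total. Xist lay between 307 and 2924 CPM (read counts scaled to a common library total) in the 21 libraries, and Ddx3y, Eif2s3y, Kdm5d and Uty on the Y chromosome had 0 CPM in each. The labels do not say that each piece came from a different animal, so p-values measure the spread between these samples.

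Other tissues were present in some pieces. The skeletal muscle score (mean log2 CPM of 13 genes) was 6.94 in MYC-NeuNT tumor 6, 9.13 in MYC-NeuNT tumor 13 and 8.12 in NeuNT tumor 2, above the 5.72 of the lowest normal gland. MYC-NeuNT tumor 8 had a B and plasma cell score of 5.93, above the 4.37 of the lowest normal gland, and the other tumors lay at or below -0.21. In the normal glands no abundant transcript of NeuNT tumor 1 was absent. Each of the 475 genes above 300 CPM in that tumor reached at least 8.31% of its tumor level in normal gland 1, where kallikrein gene Klk10 was lowest. The corresponding lowest shares were 1.71% (Klk6) in normal gland 2 and 2.19% (Klk10) in normal gland 3. NeuNT tumor 2, the tumor with the next highest values, gave 2.44%, 1.33% and 1.90%.

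The tumor genotypes were compared to find which genes differ when MYC is activated together with NeuNT. The clearest difference was a set of genes beside Erbb2 on chromosome 11, whose transcripts were 12.7 to 84.9 times as abundant in NeuNT tumors. Stard3, a cholesterol carrier of endosomes (chromosome 11, 98219682 to 98242426, mm9), averaged 53.8 ± 15.1 CPM (SD, n = 14) in MYC-NeuNT tumors and 4574 ± 2881 CPM (SD, n = 4) in NeuNT tumors, a log2 difference of -6.41 (SE 0.303, adjusted p = 2.2e-10). Pgap3, which remodels glycolipid anchors, had a log2 difference of -6.27 (adjusted p = 3.88e-09). Grb7, an adaptor that binds ERBB2, averaged 261 ± 103 against 3329 ± 1760 CPM (-3.67, adjusted p = 1.25e-06). Each of these genes was lower in all 14 MYC-NeuNT tumors than in any NeuNT tumor. Over the whole transcriptome, 59 of 14927 genes passed the test, 14 higher and 45 lower in MYC-NeuNT tumors, and 1564 had an unadjusted p under 0.05. DESeq2 called 171 higher and 132 lower genes, and on simulated counts for this comparison it made 45 false calls where edgeR made 3. There DESeq2 recovered 154 of 200 planted genes, and edgeR 14, 29, 41 and 40 of 50 at the 4 fold sizes. Those counts were drawn with dispersions that edgeR had estimated.

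The list of Erbb2 neighbours fell as a group in MYC-NeuNT tumors: 8 of its 14 tested members were lower and 0 higher, or 9 lower and 3 higher adjusted over the list alone (camera, adjusted p = 2.4e-65; adjusted p = 8.22e-10 with an estimated correlation). Besides Stard3, Pgap3 and Grb7, the lower members were Med1, a Mediator subunit (-5.47, adjusted p = 1.09e-06), Ppp1r1b, a phosphatase inhibitor (-5.05, adjusted p = 0.00119), Fbxl20 (-4.58), Mien1 (-4.47) and the transcription kinase Cdk12 (-4.30). Erbb2 itself (98273798 to 98299030) did not pass, at 729 ± 283 CPM (SD, n = 14) against 1481 ± 923 CPM (SD, n = 4), adjusted p = 0.33. The labels do not say where the NeuNT allele sits, and the Erbb2 count holds only reads assigned to the mouse gene. Among the NeuNT tumors the longest run of raised genes went from Ppp1r1b to Grb7 in tumor 1 (5 genes, 107 kb), from Fbxl20 to Grb7 in tumors 2 and 4 (8 genes, 372.8 kb) and from Cacnb1 to Grb7 in tumor 3 (10 genes, 453.9 kb). These runs, chosen for testing after the values were seen, count genes at least 1.0 log2 unit above the highest MYC-NeuNT tumor among 39 expressed genes within 1 Mb of Erbb2. E130012A19Rik in tumor 2, named after its values were seen, was raised outside the run. Erbb2, inside the runs, was not among the 39 genes, and its log2 CPM of 11.42, 9.79, 9.45 and 10.66 in NeuNT tumors 1, 2, 3 and 4 met that margin above the highest MYC-NeuNT tumor (10.14) in tumor 1 alone. With Erbb2 among the genes the raised ones formed 1 run in tumor 1, 3 in tumor 2 and 2 in each of tumors 3 and 4. Stac2, a member of the tumor 3 run, had 14670 CPM there and 291 to 606 CPM in the other NeuNT tumors.

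**Figure D1:**
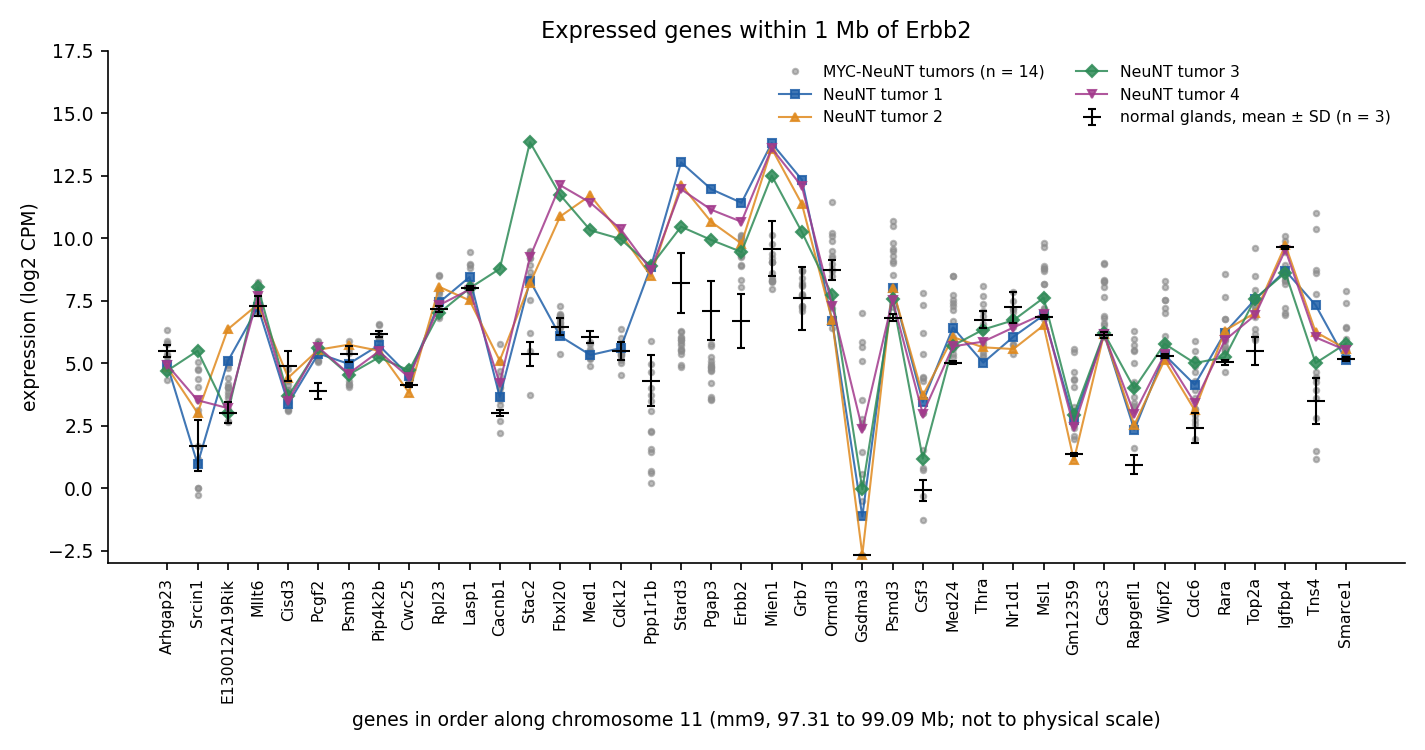
Expression (log2 CPM, y axis) of Erbb2 and the 39 expressed genes within 1 Mb of it, in their order on chromosome 11 (x axis); lines with symbols are the 4 NeuNT tumors, grey points the 14 MYC-NeuNT tumors, and bars with whiskers the mean ± SD of 3 normal glands. Stard3, Pgap3, Mien1 and Grb7 stand above all MYC-NeuNT tumors in all 4 NeuNT tumors, and Fbxl20, Med1 and Cdk12 in NeuNT tumors 2, 3 and 4.

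Away from Erbb2, Gt(ROSA)26Sor, the noncoding transcript at the Rosa26 locus that carries the MYC allele (chromosome 6, 113020393 to 113027238), fell from 24.2 ± 10.8 CPM (SD, n = 4) in NeuNT tumors to 0.395 ± 0.283 CPM (SD, n = 14) in MYC-NeuNT tumors (log2 difference -5.90, SE 0.465, adjusted p = 4.21e-07), with 4.23 ± 2.12 CPM (SD, n = 3) in normal glands. H2-Bl, a class I histocompatibility gene, averaged 0.156 ± 0.177 against 20.0 ± 19.3 CPM (-6.92, adjusted p = 8.52e-05), a value made uncertain by reads shared within that gene family. Myc transcripts averaged 229 ± 72.6 CPM in MYC-NeuNT and 157 ± 50.7 CPM in NeuNT tumors, a log2 difference of 0.54 that did not pass (adjusted p = 0.479), and 8 of 14 MYC-NeuNT tumors lay above all NeuNT tumors. The labels do not say whether the MYC allele is mouse or human, and the Myc count holds only reads assigned to the mouse gene. Genes higher in MYC-NeuNT tumors included the ribosomal protein gene Rpl35a (4.91, adjusted p = 7.67e-05), the chaperone gene Hspa8 (2.68, adjusted p = 0.00103) and the phosphatase gene Cdc14b (1.71, adjusted p = 0.00569). Rpl35a and Hspa8 have many processed pseudogenes that can share their reads, and their values of 20.5 and 269 CPM are uncertain. Mina (1.32, adjusted p = 0.0198), its overlapping neighbour Crybg3 (1.61, adjusted p = 0.0232) and Gcfc2 (1.33, adjusted p = 0.037) were higher too. Reads in the stretch that this pair shares (chromosome 16, 59490601 to 59492277) cannot be told apart without strand. Gcfc2 lost its call in 11 of the 18 fits that left out a tumor, and Crybg3 and Mina lost theirs without NeuNT tumor 1, 2 or 3.

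Proliferation genes were lower as a group in MYC-NeuNT tumors, with a median log2 difference of -0.48 over 28 members (camera, adjusted p = 3.86e-07; adjusted p = 0.97 with an estimated correlation). No single member passed, over all genes or adjusted over the list alone (0 of 28), and Mki67, the marker of cycling cells, had 222 ± 126 against 230 ± 46.7 CPM (adjusted p = 0.977). The other 30 of 32 lists tested did not pass, from adipocyte and MYC-induced biosynthesis genes (adjusted p = 0.0545 for both) upward. Several epithelial identity genes had no called change. They were Krt8 (-0.58, adjusted p = 0.538), Krt5 (5.09, SE 2.94, adjusted p = 0.55), Krt14 (2.67, adjusted p = 0.659), Cdh1 (-0.19, adjusted p = 0.837), Vim (-0.29, adjusted p = 0.871), Esr1 (0.49, adjusted p = 0.827) and the milk casein gene Csn2 (1.63, adjusted p = 0.787). Without MYC-NeuNT tumor 8 the differences were 0.67 for Krt5 and 1.16 for Krt14. The difference of Csn2 was 0.83 without tumor 2 and 0.95 without tumor 4. Pgr, at 0.276 and 0.593 CPM, was below the count filter. Milk proteins, Wnt targets and squamous keratinocyte genes had a positive median and a downward test, lipid synthesis a mean of -0.05 with an upward test, and tissue handling genes a median of 0.00, a mean of 0.03 and a downward test. The count of 59 genes was 92 with all 21 libraries in 1 fit, 34 in a test against a fold change of 1.5, 100 without MYC-NeuNT tumor 1, 29 without NeuNT tumor 2 and 30 without the 4 tumors that held muscle or lymphoid markers.

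MYC-NeuNT tumors were compared with normal glands, whose parity and stage are not given, to list what differed in tumors with both oncogenes. Levels are those of whole pieces of tissue, and adipocyte scores averaged 1.61 in these tumors and 10.49 in normal glands. Genes that rose or fell may therefore reflect cell content or changes within cells, which cannot be told apart here. Myc, Erbb2, the keratin genes Krt8 and Krt18 and 17 of 20 ERBB and MAPK feedback genes were higher in the tumors, and all 15 adipocyte genes were lower (camera, adjusted p = 0.0113 for both lists with an estimated correlation). Also lower were 13 of 16 T and NK cell genes and 5 of 12 hormone sensing genes, in lists whose calls were lost with an estimated correlation (adjusted p = 0.489 and 0.0842). Myc rose from 72.7 ± 17.9 CPM (SD, n = 3) to 229 ± 72.6 CPM (SD, n = 14), a log2 difference of 1.64 (SE 0.315, adjusted p = 0.00118), and Erbb2 from 126 ± 102 to 729 ± 283 CPM (2.52, SE 0.529, adjusted p = 0.00242). All 14 tumors lay above all normal glands for both genes. The leptin gene Lep fell from 627 ± 233 to 0.368 ± 0.417 CPM (-10.70, adjusted p = 1.23e-08). In all, 3936 of 15655 genes passed, 1906 higher and 2030 lower. Limma voom with group variances called 7714 (3508 higher and 4206 lower), and a test against a fold change of 1.5 called 2070.

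Growth-signalling genes rose. In the ERBB and MAPK feedback list, 17 of 20 members were higher and 0 lower, 19 adjusted over the list alone (camera, adjusted p = 3.62e-09; adjusted p = 0.0113 with an estimated correlation). They included the ligand genes Tgfa (3.54, adjusted p = 5.66e-05) and Hbegf (3.96) and the ETS factor gene Etv4 (3.63, adjusted p = 0.000126). Proliferation genes rose too, 17 of 28 higher and 21 adjusted over the list alone (adjusted p = 2.04e-06; adjusted p = 0.543 with an estimated correlation), among them Plk1, a mitotic kinase (2.06, adjusted p = 0.00266), Cenpe, a kinetochore motor (1.71, adjusted p = 0.00692), and Mki67 (1.90, adjusted p = 0.0195). The calls of Cenpe (adjusted p = 0.0522) and Mki67 (0.107) were lost without normal gland 3. Without normal gland 2 those of Mki67 (0.0821) and of the hypoxia gene Ankrd37 (0.0516) were lost. Of 30 ribosome biogenesis genes, 8 were higher and 1, Bysl, lower, with the same counts adjusted over the list alone (adjusted p = 0.0105; adjusted p = 0.543 with an estimated correlation). The nucleolar genes Nop56 (0.93, adjusted p = 0.00234) and Mybbp1a (0.98, adjusted p = 0.00279) led them. Hypoxia and glycolysis genes rose, 7 of 16 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.00923; adjusted p = 0.543 with an estimated correlation), with the carbonic anhydrase gene Car9 at 70.6 ± 44.6 CPM against 4.52 ± 2.45 CPM (3.95, adjusted p = 0.00426) and Ankrd37 at 2.51. Bnip3 was the member that fell (-2.28, adjusted p = 0.00159). Immediate-early genes of the tissue handling list, which also respond to growth signals, were 5 of 12 higher over all genes and adjusted over the list alone (adjusted p = 0.0212; adjusted p = 0.489 with an estimated correlation), led by Junb (2.32) and Fos (1.74).

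Of 18 epithelial junction genes 15 were higher in MYC-NeuNT tumors, 17 adjusted over the list alone (camera, adjusted p = 4.19e-10; adjusted p = 0.196 with an estimated correlation), including the cadherin gene Cdh1 (2.02, adjusted p = 0.0021), the trafficking gene Rab25 (3.14) and the membrane protease gene St14 (2.42). Luminal epithelium genes rose, 4 of 14 higher over all genes and over the list alone (adjusted p = 0.0257; adjusted p = 0.489 with an estimated correlation), with keratin genes Krt8 at 804 ± 347 against 149 ± 35.4 CPM (adjusted p = 0.000743) and Krt18 (2.35, adjusted p = 0.0013). The luminal progenitor and alveolar list (adjusted p = 0.172) and the basal and myoepithelial list (adjusted p = 0.123) did not pass. In the same comparison the adipocyte list had a median log2 difference of -9.08. The hormone sensing list fell, with 5 members lower and 1 higher of 12, 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.00481; adjusted p = 0.0842 with an estimated correlation). The progesterone receptor gene Pgr fell from 17.2 ± 5.55 to 0.276 ± 0.286 CPM (-5.93, adjusted p = 9.18e-06), the estrogen receptor gene Esr1 by 2.53 on the log2 scale (adjusted p = 0.0115) and Calca, a calcitonin peptide gene of secretory differentiation, by 8.76 (adjusted p = 3.92e-06). Prom1 was the member that rose (2.33, adjusted p = 0.0459), and Esr1 lost its call without normal gland 1 (adjusted p = 0.0736). Krt5 (3.83, SE 3.09, adjusted p = 0.37), Krt14 (4.73, adjusted p = 0.185), Vim (-0.79, adjusted p = 0.314) and Csn2 (0.33, adjusted p = 0.918) did not pass. Without MYC-NeuNT tumor 8 the differences were -0.59 for Krt5 and 3.22 for Krt14. That of Csn2 turned without MYC-NeuNT tumor 2 (-0.49) or 4 (-0.35) or normal gland 1 (-0.16) or 2 (-0.24) and was 3.52 without normal gland 3. Grb7 had 261 ± 103 against 252 ± 227 CPM (adjusted p = 0.951), a log2 difference of 0.04 that lay between -0.33 (without normal gland 2) and 1.09 (without normal gland 1) with a library left out. Genes above 300 CPM in NeuNT tumor 1 reached at least 1.71% of its level in each of these glands. With the lowest share of that tumor subtracted from each normal gland, an alternative added after seeing the data, Grb7 was higher by 2.04 (adjusted p = 0.0143) and Erbb2 by 4.81 (adjusted p = 9.3e-06).

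All 15 adipocyte genes fell in MYC-NeuNT tumors, also adjusted over the list alone (camera, adjusted p = 6.48e-27; adjusted p = 0.0113 with an estimated correlation), among them Plin1, which coats lipid droplets (-9.53), Retn (-9.66), Pck1 (-9.79) and the lipase gene Lipe (-6.38, adjusted p = 1.05e-10). In the lipid synthesis list 8 members fell and 4 rose of 15, over all genes and over the list alone (adjusted p = 0.00923; adjusted p = 0.353 with an estimated correlation). Dgat2 (-5.97) and Acaca (-3.11), for triglyceride and fatty acid synthesis, were lower, and the cholesterol gene Sqle (1.95) higher. T and NK cell genes fell, 13 of 16 lower and 15 adjusted over the list alone (adjusted p = 9.35e-07; adjusted p = 0.489 with an estimated correlation), among them Cd4 (-3.72) and Cd28 (-4.15). B and plasma cell genes were 2 of 12 lower, Jchain (-5.33) and Pax5 (-3.79), and 4 adjusted over the list alone (adjusted p = 0.00046; adjusted p = 0.543 with an estimated correlation), while MYC-NeuNT tumor 8 held B cell transcripts at the level of normal glands. Pax5 was at -7.23 without that tumor and Jchain at -3.47 without normal gland 3. Fibroblast and matrix genes were 6 of 18 lower, also adjusted over the list alone (adjusted p = 0.000602; adjusted p = 0.563 with an estimated correlation), led by the proteoglycan gene Dcn (-4.06) and Dpt (-4.81). Endothelium genes were 3 of 12 lower, 4 adjusted over the list alone (adjusted p = 0.0332; adjusted p = 0.61 with an estimated correlation), including the angiopoietin receptor gene Tek (-3.07) and Cldn5 (-2.18). All 5 red blood cell genes fell, also adjusted over the list alone (adjusted p = 0.00481; adjusted p = 0.489 with an estimated correlation), with Hbb-b2 at -3.61, uncertain because globin copies share reads, and Alas2 at -2.75. Both lost their calls without normal gland 1 (-2.40, adjusted p = 0.135, and -1.36, adjusted p = 0.24). Antigen presentation genes fell as a list with 0 of 14 members called, 0 adjusted over the list alone (adjusted p = 0.0377; adjusted p = 0.61 with an estimated correlation).

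Among single genes outside these lists, Gsdma3, a gasdermin gene of chromosome 11, had 22.1 ± 35.9 CPM in tumors and 0 counts in normal glands, at least 306-fold higher against a floor of 3 counts over the group. Acan, the cartilage proteoglycan aggrecan, had 668 times the normal level from 3 counts there (95% counting interval 229 to 3240) and was lost without any of MYC-NeuNT tumors 5, 7, 11, 12 and 14. The secreted protein genes Fetub (7.01, adjusted p = 0.0179) and Ahsg (6.77, adjusted p = 0.0313), adjacent on chromosome 16, were higher. Atp6v0c (7.84, adjusted p = 1.48e-05) and its copy Atp6v0c-ps2 (395 times, interval 135 to 1920) share nearly all their sequence and are uncertain. Mrgprg, an orphan receptor gene, had 1 count over the 14 tumors and was 8600 times as abundant in normal glands (interval 1540 to 340000), and the albumin gene Alb fell by 10.30 on the log2 scale (adjusted p = 1.85e-09). Intervals and floors cover counting error only. The other 16 of 32 lists did not pass, with adjusted p from 0.0511 for skeletal muscle to 0.82 for squamous keratinocyte genes. Milk proteins, basal, interferon and Wnt genes had a positive median and a downward test, and the Erbb2 neighbours a mean of 0.03 with a median of -0.37 and a downward test. The count of changed genes fell to 2450, 1705 and 2160 without normal gland 1, 2 or 3, and each of these ended the calls of Gsdma3, Acan, Fetub, Ahsg, Cldn5 and Pax5. It was 5943 without the 3 MYC-NeuNT tumors that held muscle or lymphoid markers.

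NeuNT tumors were compared with the same normal glands to describe the tumors that arise without activated MYC. Here too cell content cannot be told apart from changes within cells, with adipocyte scores of 2.47 in NeuNT tumors and 10.49 in normal glands. Higher in these tumors were 10 of 14 Erbb2 neighbours, 27 of 28 proliferation genes and 7 of 12 luminal progenitor and alveolar genes. Lower were all 11 B and plasma cell genes, 13 of 15 T and NK cell genes, 14 of 15 adipocyte genes and 15 of 18 fibroblast and matrix genes. These list calls were lost with an estimated correlation (camera, adjusted p = 0.383 for fibroblast and matrix genes and 0.295 for the others). Erbb2 rose from 126 ± 102 CPM (SD, n = 3) to 1481 ± 923 CPM (SD, n = 4), a log2 difference of 3.51 (SE 0.721, adjusted p = 0.00959), and Grb7 from 252 ± 227 to 3329 ± 1760 CPM (3.69, adjusted p = 0.0114; 0.0523 without normal gland 3). Myc rose from 72.7 ± 17.9 to 157 ± 50.7 CPM (1.07, adjusted p = 0.0297), and all 4 tumors were above all normal glands for these 3 genes. Of 14823 genes, 4414 passed, 1996 higher and 2418 lower, and 2934 passed a test against a fold change of 1.5.

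Of 14 tested Erbb2 neighbours 10 were higher and 1, Ormdl3, lower, also adjusted over the list alone (camera, adjusted p = 0.000493; adjusted p = 0.295 with an estimated correlation). Mien1 reached 11200 ± 3716 against 940 ± 765 CPM (3.55, adjusted p = 0.00829) and Ppp1r1b 428 ± 50.5 against 23.4 ± 17.6 CPM (4.17, adjusted p = 0.00184). Genes above 300 CPM in NeuNT tumor 1 reached at least 1.71% of its level in each of these glands, and with its lowest share subtracted the differences were 5.87 for Erbb2, 5.75 for Grb7, 4.72 for Mien1 and 6.06 for Ppp1r1b. The segment genes stood at 9.4% to 13.9% of their NeuNT tumor 1 level in normal gland 1, 1.86% to 3.33% in gland 2 and 2.97% to 4.36% in gland 3. Proliferation genes were 27 of 28 higher, also adjusted over the list alone (adjusted p = 2.94e-14; adjusted p = 0.295 with an estimated correlation), with the mitotic kinase genes Aurkb (2.36, adjusted p = 0.00218) and Cdk1 (2.45, adjusted p = 0.00246) and with Mki67 (1.93). MYC-induced biosynthesis genes were 6 of 25 higher, also adjusted over the list alone (adjusted p = 0.00753; adjusted p = 0.417 with an estimated correlation), including the kinase gene Cdk4 (1.45) and the transferrin receptor gene Tfrc (1.82). Ribosome biogenesis genes were 5 of 30 higher, 1 adjusted over the list alone (adjusted p = 0.0139; adjusted p = 0.613 with an estimated correlation), among them Mybbp1a (0.94; lost without normal gland 1 or 2, adjusted p = 0.0543 and 0.0531) and Nop2 (0.78). ERBB and MAPK feedback genes rose, 15 of 19 higher and 18 adjusted over the list alone (adjusted p = 5.24e-08; adjusted p = 0.295 with an estimated correlation), with Etv4 at 3.74 and Tgfa at 3.05. Hypoxia and glycolysis genes were 9 higher and 2 lower of 16, 12 and 2 adjusted over the list alone (adjusted p = 0.000268; adjusted p = 0.295 with an estimated correlation), led by the oxygen sensor gene Egln3 (3.89) and Pgk1 (1.85). Tissue handling genes were 4 of 12 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.0184; adjusted p = 0.5 with an estimated correlation), with Fos at 2.08 and Ier2 at 1.36.

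Luminal progenitor and alveolar genes rose, 7 of 12 higher and 8 adjusted over the list alone (camera, adjusted p = 0.00096; adjusted p = 0.295 with an estimated correlation), with Sox10, a progenitor transcription factor gene, at 795 ± 209 against 69.2 ± 38.1 CPM (3.49, adjusted p = 0.00321) and the casein gene Csn3 (2.98). The adipocyte list had a median log2 difference of -7.34 in the same comparison. Luminal epithelium genes were 5 of 14 higher, also adjusted over the list alone (adjusted p = 0.00154; adjusted p = 0.295 with an estimated correlation), including Krt8 (2.98) and Krt18 (2.90). Epithelial junction genes were 15 of 18 higher, 17 adjusted over the list alone (adjusted p = 1.5e-11; adjusted p = 0.295 with an estimated correlation), with the claudin gene Cldn3 at 669 ± 27.8 against 58.2 ± 25.9 CPM (3.49) and Cdh1 at 2.18. Hormone sensing genes fell, 6 lower and 1 higher of 12, also adjusted over the list alone (adjusted p = 0.0235; adjusted p = 0.358 with an estimated correlation), with the pioneer factor gene Foxa1 (-5.82), Esr1 (-3.04) and Pgr (-4.83) lower. Mesenchymal transition genes fell, 7 of 14 lower, with 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.000237; adjusted p = 0.383 with an estimated correlation), led by the E-cadherin repressor genes Zeb1 (-2.86) and Zeb2 (-3.31), whereas Vim did not pass (-0.52, adjusted p = 0.302). Krt5 (-1.25, adjusted p = 0.485), Krt14 (2.05, adjusted p = 0.392) and Csn2 (-1.35, adjusted p = 0.586) did not pass either. Csn2 was at 1.87 without normal gland 3.

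All 11 tested B and plasma cell genes fell, also adjusted over the list alone (camera, adjusted p = 3.36e-15; adjusted p = 0.295 with an estimated correlation). Cd79b, part of the B cell receptor, fell from 118 ± 45.8 to 1.23 ± 0.709 CPM (-6.61, adjusted p = 0.00104), and Cr2 was 3210 times as abundant in normal glands (interval 576 to 127000), from 1 count in tumors. T and NK cell genes were 13 of 15 lower, also adjusted over the list alone (adjusted p = 6.52e-13; adjusted p = 0.295 with an estimated correlation), with Cd4 (-4.59) and Cd8a (-5.96). Macrophage genes were 6 of 14 lower, also adjusted over the list alone (adjusted p = 0.00991; adjusted p = 0.501 with an estimated correlation), led by the scavenger receptor gene Cd163 (-2.93) and Itgam (-2.25). Antigen presentation genes were 4 of 14 lower, also adjusted over the list alone (adjusted p = 0.0466; adjusted p = 0.601 with an estimated correlation), all of class II: Ciita, its transactivator gene (-1.88), H2-Eb1 (-4.30), H2-Aa and H2-Ab1 (-1.50 each). Ciita (adjusted p = 0.0572) and H2-Eb1 (0.0531) lost their calls without normal gland 3. Adipocyte genes were 14 of 15 lower, also adjusted over the list alone (adjusted p = 1.03e-10; adjusted p = 0.295 with an estimated correlation), with Lep (-9.40) and the adipocyte regulator gene Pparg (-6.24). Fibroblast and matrix genes were 15 of 18 lower, also adjusted over the list alone (adjusted p = 4.73e-07; adjusted p = 0.383 with an estimated correlation), with Pdgfra (-3.38) and Thy1 (-2.87). Endothelium genes were 5 of 12 lower, 7 adjusted over the list alone (adjusted p = 0.00291; adjusted p = 0.483 with an estimated correlation), with Cldn5 (-3.19) and Tek (-2.94).

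Single genes with the widest differences included the matrix collagen gene Col11a1 (663 ± 739 against 11.2 ± 6.51 CPM, adjusted p = 0.027), Stac2 (6.52, adjusted p = 0.0301), Fetub (6.33), Scrg1 (6.53), Cd177 (5.89) and the pseudogene Gpx2-ps1 (6.18), whose reads can come from its parent gene. In the other direction, 0 counts were found over the 4 tumors for Prr32 (at least 314-fold lower), Hoxa10 (191-fold), Apoc3 (187-fold) and Trim12a (151-fold), each a lower bound, and 1 count for Mrgprg (2190 times as abundant in normal glands, interval 393 to 86600). The other 13 of 32 lists did not pass, with adjusted p from 0.0864 for p53 targets and apoptosis to 0.918 for neutrophil genes. Neutrophil genes had a median of -0.87 and an upward test, interferon genes a median of 0.07 and a downward test, and amino acid supply genes a mean of -0.10 and an upward test. The count of changed genes was 2870, 2431 and 2521 without normal gland 1, 2 or 3, and each of these ended the calls of Myc, Pgr, Stac2, Fetub, Cd177, Col11a1 and Nop2. Stac2 was at 3.22 without NeuNT tumor 3 (adjusted p = 0.00321), and Scrg1 lost its call without normal gland 2 or 3 (adjusted p = 0.0746 and 0.0793). Leaving out NeuNT tumor 1 also ended the call of Myc, and leaving out NeuNT tumor 4 that of Col11a1.

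**Figure D2:**
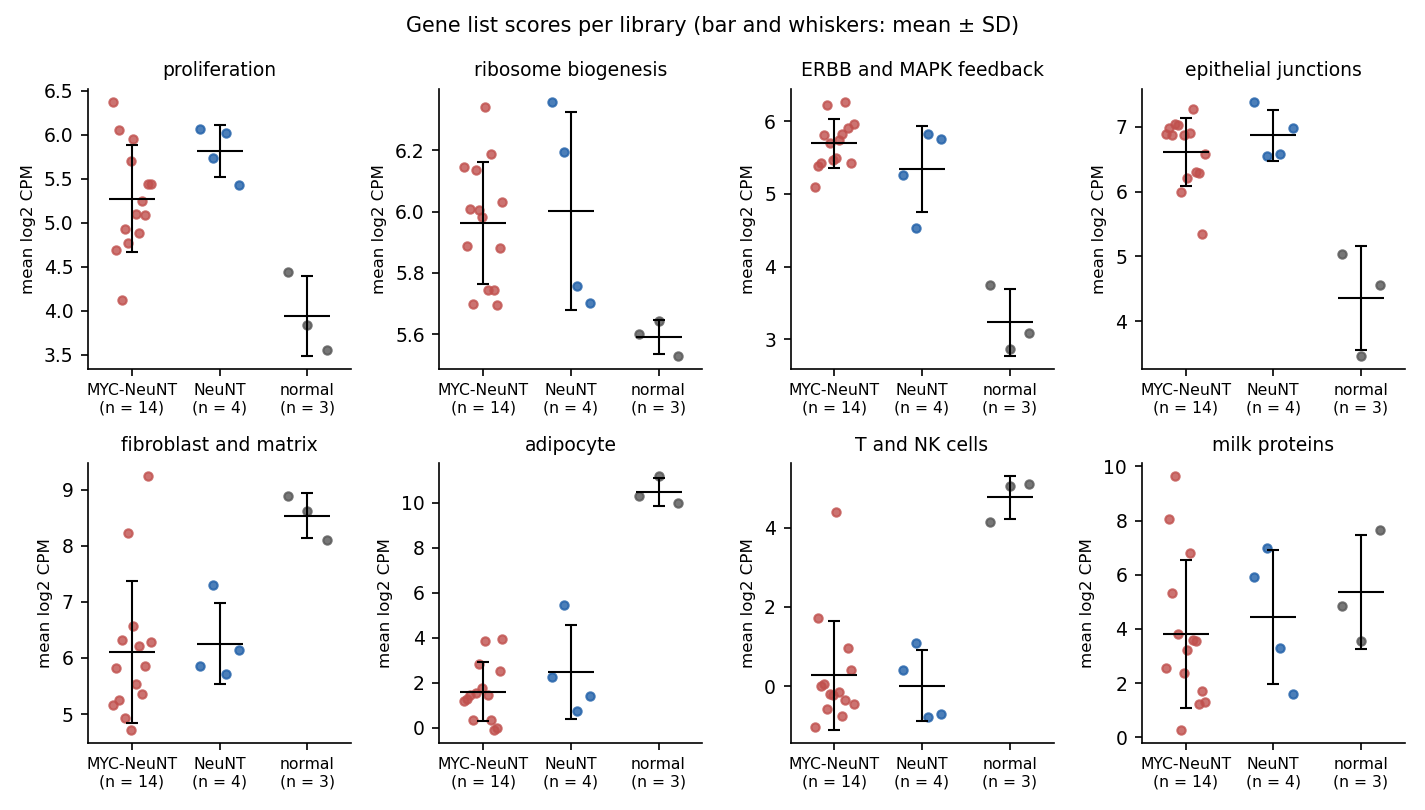
Scores of 8 gene lists (mean log2 CPM of the members, y axis) in each library by group (x axis); points are libraries, and bars with whiskers the mean ± SD of 14 MYC-NeuNT tumors, 4 NeuNT tumors and 3 normal glands. Adipocyte scores averaged 1.61, 2.47 and 10.5 in these groups, and milk protein scores ranged from 0.27 to 9.65 among MYC-NeuNT tumors.

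Both tumor genotypes changed many genes against the same 3 normal glands. Of 14792 genes tested in both, 1191 were higher and 1499 lower in both, among them Erbb2, Myc, Etv4, Tgfa, Krt8 and Krt18 upward and Lep, Pgr, Cd4 and Dcn downward. Independent lists would share 248.6 and 328.4 genes in the 2 directions. In 20 simulations of unchanged groups against shared controls 0 genes were shared. Unchanged groups give few calls that could be shared, so this 0 does not measure how far shared controls make real calls overlap. In these simulations the fold changes correlated across genes, which are not independent replicates, at 0.652 on average, against 0.885 observed. Their covariance was 2.445, against 0.181 in the simulations. Part of the excess over either value may come from the shared controls, which were too few to split. Another 5 genes were called in opposite directions: Stard3 (-2.82 in MYC-NeuNT and 3.56 in NeuNT tumors), Pgap3 (-2.62 and 3.62), Med1 (-0.69 and 4.78), Gt(ROSA)26Sor (-3.40 and 2.49) and H2-Bl (-3.33 and 3.56). The normal glands carried the MYC allele at Rosa26 and the NeuNT tumors were without MYC. For Gt(ROSA)26Sor in NeuNT tumors, the effects of tumor and allele therefore cannot be told apart. Med1 had 39.9 CPM in NeuNT tumor 1, below the 58.9 CPM of the lowest normal gland, so its rise rests on NeuNT tumors 2, 3 and 4. With the NeuNT tumor 1 share subtracted from normal glands, 2 genes were called in opposite directions, Gt(ROSA)26Sor (-3.37 and 2.59) and Med1 (-0.74 and 4.78). Stard3 (-0.38, adjusted p = 0.452) and Pgap3 (0.07, adjusted p = 0.931) then did not pass in MYC-NeuNT tumors, and H2-Bl was below the count filter there.

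The series title names heterogeneity among these tumors. The 12 most variable genes among MYC-NeuNT tumors were mainly of milk, skeletal muscle and squamous epithelium. Glycam1, a milk mucin gene, ranged from 0.146 to 4001 CPM between MYC-NeuNT tumors 7 and 4, and the casein genes Csn1s2a (0.768 to 7410 CPM) and Csn2 (2.69 to 16510 CPM) were lowest in tumor 6. The muscle genes Myh4, Acta1, Tnnc2, Tnnt3 and Ckm were highest in tumors 13 and 6, which held muscle. Krt6a, a keratin of stratified epithelium, reached 1922 CPM in tumor 8, which also held lymphoid markers, against a median of 1.44 CPM, and Tmprss11e reached 232 CPM in tumor 6. St6galnac1, a sialyltransferase gene, ranged from 0 to 187 CPM and Acan from 0 to 231 CPM. By list, milk protein scores ran from 0.27 (tumor 6) to 9.65 (tumor 4), Wnt target scores from 0.97 (tumor 1) to 6.21 (tumor 10), and ribosome biogenesis scores only from 5.70 (tumor 12) to 6.34 (tumor 8).

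Tumors of one genotype were not shown to be more alike than those of the other. The mean pairwise distance (1 minus the Pearson correlation over 2000 variable genes) was 0.394 among the 14 MYC-NeuNT tumors and 0.278 among the 4 NeuNT tumors, a difference of 0.116 (two-sided exact permutation test over all splits, p = 0.339). The 3 normal glands lay 0.0776 apart. MYC-NeuNT tumors 6, 8 and 13, those with muscle or lymphoid markers, were the farthest from their group, at 0.575, 0.559 and 0.522, and without them and NeuNT tumor 2 the difference was 0.0238 (p = 0.819, exact permutation test). For the spread of list scores, 0 of 33 lists differed between genotypes after adjustment (exact permutation test), and 1 had an unadjusted p under 0.05, the Erbb2 neighbours (SD 0.269 against 0.643, p = 0.0114, adjusted p = 0.377).

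Relations between gene groups were tested across the 14 MYC-NeuNT tumors in 8 pairs fixed in advance. Myc transcripts rose with the ribosome biogenesis score (Pearson r = 0.626, permutation p = 0.0163, adjusted p = 0.0436; Spearman rho = 0.679, p = 0.00995, adjusted p = 0.0796), and r was 0.617 (p = 0.0342) without tumors 10 and 13. The adjusted p lay above 0.05 in 11 of the 14 runs that left out a tumor, up to 0.122 without tumor 12. Epithelial junction scores fell as mesenchymal transition scores rose (r = -0.765, permutation p = 0.00119, adjusted p = 0.00952; rho = -0.516, p = 0.0617, adjusted p = 0.247). They also fell with fibroblast and matrix scores (r = -0.768, permutation p = 0.00303, adjusted p = 0.0121; rho = -0.433, p = 0.124, adjusted p = 0.31). Both relations rest on tumors 6 and 13, which held muscle. Without them r was -0.515 (p = 0.0887) and -0.21 (p = 0.507). Without tumor 13 alone the adjusted p values were 0.0598 and 0.144, and without tumor 6 the second was 0.0511. Proliferation with ribosome biogenesis (r = 0.493, adjusted p = 0.145) and Erbb2 with ERBB and MAPK feedback (r = 0.36, adjusted p = 0.327) did not pass by permutation. Nor did luminal with basal genes (r = -0.062), proliferation with T and NK cell genes (r = 0.102) and ribosome biogenesis with antigen presentation (r = -0.045), each with an adjusted p of 0.88. Without tumors 6, 8 and 13, which had muscle or lymphoid markers, r was 0.673 (adjusted p = 0.0943, permutation) for luminal with basal genes and -0.413 (adjusted p = 0.416) for proliferation with T and NK cell genes.

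Neighbouring genes on chromosomes 6 and 11 were raised together in single MYC-NeuNT tumors, in a test whose method and chromosomes were chosen after the values were seen. In windows of 25 expressed genes, 13 of 14 MYC-NeuNT tumors had a block on either chromosome whose median rose above all 1000 shuffles of the gene order. Chromosome 11 blocks near its end reached a log2 median of 2.64 in tumor 10 (119951836 to 121578703, Enthd2 to Metrnl) and 2.49 in tumor 4 (119176101 to 121578703, Card14 to Metrnl). On chromosome 6 the longest block spanned 48.1 Mb in tumor 12 (3322257 to 51408767, Samd9l to Nfe2l3, log2 median 1.59). Setd5, the gene beside Gt(ROSA)26Sor, named after its values were seen, averaged 528 ± 248 CPM (SD, n = 14) in MYC-NeuNT tumors, 176 ± 50.1 CPM (SD, n = 4) in NeuNT tumors and 81.0 ± 12.0 CPM (SD, n = 3) in normal glands. No NeuNT tumor had a block on chromosome 6, NeuNT tumor 3 had one on chromosome 11 around Erbb2, and no normal gland had one on either. MYC-NeuNT tumors 2, 4 and 8 also had chromosome 11 blocks whose coordinates covered Erbb2 (highest log2 medians 1.15, 2.02 and 1.30). Grb7, beside Erbb2, had log2 CPM of only 8.11, 7.68 and 7.28 there, below the 10.25 of the lowest NeuNT tumor. Psmd3, farther along, had 10.67, 10.49 and 9.56, above the 8.00 of the highest NeuNT tumor. Both genes were chosen after their values were seen, and block edges can lie several genes off. The runs beside Erbb2 in NeuNT tumors 1, 2 and 4 held 5 or 8 genes, so a median of 25 genes could miss them. The height that a window had to pass, the highest of the shuffles of its own library, was 1.37 to 1.55 log2 units in normal glands, 0.54 to 1.49 in MYC-NeuNT tumors and 0.54 to 1.15 in NeuNT tumors, so lower blocks could not be called in normal glands. Above 1.55, 9 MYC-NeuNT tumors and 1 NeuNT tumor had a block on chromosome 6 or 11. On other chromosomes, NeuNT tumor 1 had 4 blocks (chromosomes 4 and 17), NeuNT tumor 2 had 1 (chromosome 17) and NeuNT tumor 4 had 3 (chromosomes 12 and 18), so that all 4 NeuNT tumors had a block. Chromosome 4 had blocks in 4 MYC-NeuNT tumors and 1 NeuNT tumor, chromosome 6 in 7 and 0, and chromosome 11 in 10 and 1.

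**Figure D3:**
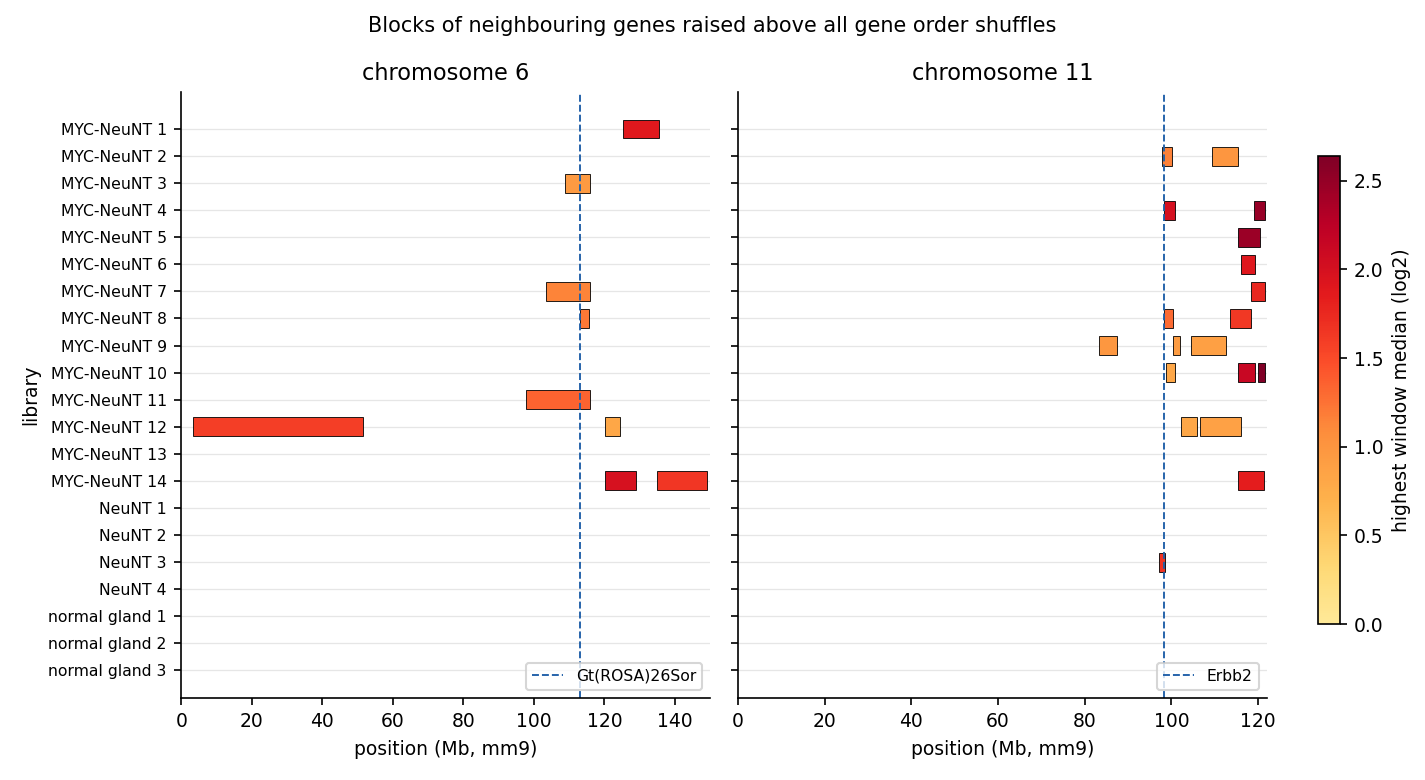
Position (Mb, mm9, x axis) of blocks of neighbouring genes raised above all gene order shuffles on chromosomes 6 and 11 in each library (y axis); bar colour gives the highest 25-gene window median (log2), and dashed lines mark Gt(ROSA)26Sor and Erbb2. On these chromosomes blocks appear in 13 of 14 MYC-NeuNT tumors, in NeuNT tumor 3 and in no normal gland, where a window had to pass 1.37 to 1.55 against 0.54 to 1.49 in MYC-NeuNT tumors; NeuNT tumors 1, 2 and 4 had blocks on other chromosomes.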

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

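The tests of a gained stretch, of transgene reads and of normalization for the Erbb2 interval, and both tests of the NeuNT tumor 1 share in normal glands, were chosen only after the results were seen.

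The genes beside Erbb2 stood far higher in NeuNT than in MYC-NeuNT tumors. Reads of the NeuNT transgene counted on mouse genes would leave the neighbours of Erbb2 near 0, but over the 13 tested members of the neighbour list other than Erbb2 the median log2 difference was -4.30 (upper quartile -1.08), beyond the -1.02 of Erbb2. A normalization factor moves all genes of a library alike, but this median lay -4.37 from that of all other tested genes. A candidate explanation is a gain of 1 stretch of chromosome 11 around Erbb2 in each NeuNT tumor: the share of shuffles of the gene order with as few separate runs of raised genes was 0.0001 in each of the 4 tumors, the smallest that 10000 shuffles can give, and at most 0.0004 with Erbb2, first left out, among the genes. Erbb2 inside the runs was raised by the same margin in tumor 1 alone, DNA copy number was not measured, and time to tumor, which goes with genotype, stays open as untested.

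Each of the 475 genes above 300 CPM in NeuNT tumor 1 reached at least 8.31% of its tumor level in normal gland 1, 1.71% in gland 2 and 2.19% in gland 3, and these lowest shares lay above those of each other tumor there. The highest lowest share between tumors was 17.3%, of MYC-NeuNT tumor 3 in MYC-NeuNT tumor 2, and NeuNT tumor 1 in NeuNT tumor 2 gave 7.86%. Shares of this size are thus not by themselves a sign of carry-over. The glands' own expression was tested by how far log2 ratios of gland to tumor varied over the chromosome 11 genes raised in NeuNT tumor 1. Their SD was at most 0.322, where the gene-by-gene median of the MYC-NeuNT tumors gave 2.055. A gain that raised these genes alike in NeuNT tumor 1 would also leave even ratios, so this test cannot decide. RNA or reads of NeuNT tumor 1 in the normal gland libraries may be the source, although over 6665 genes above 30 CPM in it a few fell short, such as H2-Bl in gland 1 (28 reads against 51.6 predicted), Chit1 in gland 2 (1 against 9.45) and Klk14 in gland 3 (8 against 16.7). Whether RNA, reads or tissue carried over was not tested.

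Genes with opposite changes against normal glands differed between the genotypes in the direct test: Stard3 by -6.41, Pgap3 by -6.27, Gt(ROSA)26Sor by -5.90, Med1 by -5.47 and H2-Bl by -6.92 (log2). Since the normal glands carried the MYC allele at Rosa26 and the NeuNT tumors were without MYC, the rise of Gt(ROSA)26Sor in NeuNT tumors cannot be told apart from the allele. With the NeuNT tumor 1 share subtracted from normal glands, Gt(ROSA)26Sor and Med1 kept opposite calls, Stard3 and Pgap3 did not pass in MYC-NeuNT tumors (-0.38 and 0.07), and H2-Bl was below the count filter there. The rise of Med1 rests on NeuNT tumors 2, 3 and 4, since NeuNT tumor 1 had 39.9 CPM, below the 58.9 CPM of the lowest normal gland.

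Among 130 values tested over the 4 NeuNT tumors, 10 had a tumor far from the others, where chance gives about 1 in 20 groups. The gap as a share of the range was 0.906 for Atp6v0c and 0.917 for Atp6v0c-ps2, both high in tumor 3. It was 1.0 for Cr2 in tumor 3 and 1.0 for Mrgprg in tumor 1, each from a single count. In tumor 2, which held muscle, the skeletal muscle score (0.854), the adipocyte gene Plin1 (0.908) and the matrix gene Dcn (0.883) were high. H2-Eb1 was high (0.857) and Mien1 low (0.834) in tumor 3, and Gt(ROSA)26Sor was low in tumor 1 (0.881).

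Other splits of the same libraries were drawn for the counts of changed genes. Between genotypes 3 of 100 splits, the real one included, called at least the real 59, a share under 0.05. The highest other called 1358, with MYC-NeuNT tumors 6, 8, 11 and 13 as the smaller group, so the count alone does not exclude chance. The split that called 1358 points to a structure of the samples, and tumors 6, 8 and 13 are the MYC-NeuNT tumors with muscle or lymphoid markers. For MYC-NeuNT tumors against normal glands 1 of 100 splits, the real one, reached 3936 (highest other 22), which argues against chance. For NeuNT tumors 1 of 35, the real one, reached 4414 (highest other 2136). These 35 are all possible splits, so no smaller share could occur, and chance is not excluded there.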

How the results depend on the processing

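The fits without tumors that held muscle or lymphoid markers, with the transcript of median count and with the NeuNT tumor 1 share subtracted were chosen only after the results were seen. Between tumor genotypes, where 59 genes passed, DESeq2 called 303 (171 higher), limma on FPKM 74 (25 higher) and 70 (33 higher) with pseudocounts of 1 and 0.1, the fit of all 21 libraries 92, the test against a fold change of 1.5 34, and the fit without tumors with muscle or lymphoid markers 30. Leaving out each library gave 29 (without NeuNT tumor 2) to 100 (without MYC-NeuNT tumor 1). For MYC-NeuNT tumors against normal glands (3936) voom called 7714, the test against a fold change of 1.5 2070, and the fit without marked tumors 5943. Leaving out a library gave 1705 (without normal gland 2) to 4601 (without MYC-NeuNT tumor 8), with 2450 without normal gland 1 and 2160 without normal gland 3. For NeuNT tumors against normal glands (4414) the test against a fold change gave 2934, and leaving out a library 2431 (normal gland 2) to 5343 (NeuNT tumor 2), with 2870 and 2521 without normal glands 1 and 3. Fits that left out libraries had fewer samples, and otherwise the cause was not tested.

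For lists, an estimated correlation left 1 of 2 calls between genotypes, 2 of 16 for MYC-NeuNT tumors and 0 of 19 for NeuNT tumors against normal glands. Fry kept 1, 14 and 17 of these calls among its 1, 17 and 20. It lost proliferation (0.944) between genotypes, endothelium (0.0584) and antigen presentation (0.0609) in MYC-NeuNT tumors, and ribosome biogenesis and antigen presentation (0.0964 each) in NeuNT tumors (adjusted p). Leaving out a library gave 2 to 6 lists between genotypes, with 6 without NeuNT tumor 4, 5 without NeuNT tumor 1 or 3 and 4 without MYC-NeuNT tumor 7, 8 or 13. The other ranges were 14 to 21 and 18 to 23. Antigen presentation lost its call in MYC-NeuNT tumors without tumor 1, 8 or 13 or normal gland 3, and endothelium without tumor 1 or 8. In NeuNT tumors antigen presentation lost it without tumor 4 or normal gland 3, ribosome biogenesis without tumor 1 and tissue handling without normal gland 2.

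Sample numbers did not pair the samples: correlations of same-numbered libraries were -0.279, -0.027, 0.302 and -0.263 between genotypes, -0.037, -0.165 and -0.037 for MYC-NeuNT tumors, and 0.144, 0.131 and 0.067 for NeuNT tumors against normal glands. In the last set each NeuNT tumor correlated best with its own-numbered gland, a hint from the data only. With the number as a block, edgeR called 0 genes (577 with an unadjusted p under 0.05) and 11 lists passed between genotypes, against 5 genes and 10 lists for the same libraries without a block. In the other comparisons the block gave 3709 and 2786 genes, against 5212 and 3588 without it. Krt5 in MYC-NeuNT tumors against normal glands, 3.83 with all libraries, was -3.82 with the block and -3.93 without it over the libraries with shared numbers, which leave out MYC-NeuNT tumors 4 to 14. The block moved the median of all genes by -0.128 log2 units there, and other settings by 0.1 at most.

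Across MYC-NeuNT tumors, leaving out a tumor moved r of junctions with mesenchymal transition between -0.852 (without tumor 10) and -0.68 (without tumor 13), of junctions with fibroblast genes between -0.833 and -0.536, of luminal with basal genes between -0.341 and 0.152, of proliferation with T and NK cells between -0.363 and 0.298, of ribosome biogenesis with antigen presentation between -0.207 and 0.042, of Myc with ribosome biogenesis between 0.559 and 0.719, of proliferation with ribosome biogenesis between 0.367 and 0.594 and of Erbb2 with ERBB feedback between 0.279 and 0.495. Without the marked tumors the first 4 were -0.329, 0.039, 0.673 and -0.413. Myc with ribosome biogenesis missed the threshold with median scores (0.518), RLE factors (0.609) and FPKM (0.591). Luminal with basal genes were at 0.013 with median scores and 0.083 with FPKM, proliferation with T and NK cells at -0.009 with median scores, and ribosome biogenesis with antigen presentation at 0.211 with median scores and 0.03 with RLE factors. With a tumor left out the distance difference lay between 0.0808 (without MYC-NeuNT tumor 6) and 0.147 (without NeuNT tumor 2), with exact permutation p from 0.256 to 0.666. It was 0.0269 (p = 0.532) over all filtered genes, 0.0238 (p = 0.819) without the marked tumors and 0.351 (p = 0.41) on the Euclidean scale, and 0 lists differed in spread in any setting. Among named genes with a library left out, 393, 827 and 389 values kept direction and side of the threshold in the 3 comparisons, and 17, 30 and 30 lost the call. Under the other settings 30, 17 and 22 values lost the call, and 2 turned direction, both for MYC-NeuNT tumors against normal glands. The low recovery of genes changed 2-fold limits what these depths and group sizes show.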

Other observations

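The tests of a chromosome gain and of linked strain sequence were chosen only after the results were seen, and so were the genes named here.

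Several lists that did not pass their test held members that changed in both tumor genotypes against normal glands. Among p53 targets, the cell cycle inhibitor genes Cdkn1a (1.89 in MYC-NeuNT tumors, log2, and also past the test in NeuNT tumors) and Cdkn2a (3.81 in MYC-NeuNT and 2.97 in NeuNT tumors) and Trp53 itself (0.92 and 1.01) rose, and the death receptor gene Fas fell (-2.58 and -2.98). The glutamine genes Slc1a5 (-4.99 and -4.67) and Glul (-4.76 and -4.56) fell while the amino acid transporter gene Slc7a5 rose (2.15 and 2.57). The cyclin gene Ccnd1 rose (2.58 and 2.73) and the Wnt effector gene Lef1 fell (-3.13 and -1.80). The oxytocin receptor gene Oxtr, of contractile myoepithelium, fell (-5.86 and -4.62), and so did Mycl (-3.99 and -4.99).

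Of the 59 genes that differed between tumor genotypes, 9 of 751 tested lay on chromosome 6, 9 of 1255 on chromosome 11 and 7 of 757 on chromosome 17. Those on chromosome 17 included class I histocompatibility genes H2-Q1 (-4.91), H2-T10 (-2.88) and Gm8909 (-6.42), lower in MYC-NeuNT tumors but uncertain, since related genes can share reads. On chromosome 6, which carries the MYC allele, A2m (-4.89), Pianp (-3.75), Eno2 (-2.72) and Tril (-2.37) were lower and Gcfc2 (1.33) higher.

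Blocks of neighbouring genes on chromosomes 6 and 11 stood higher in single MYC-NeuNT tumors. With 1 gene kept per family name, 13 of 14 tumors kept such a block, which argues against clusters of like-named genes alone. This step kept 10121 of 10865 genes, and neighbours with unlike names that are expressed together were not tested. Strain sequence linked to the MYC allele would give all tumors a like window around Gt(ROSA)26Sor. That window ranged over 1.53 log2 units, against at most 1.0 in shuffles, so the tumors were not alike there. It overlaps blocks of MYC-NeuNT tumors 3, 7, 8 and 11, so this range cannot rule out strain sequence beneath them. Chromosome 11 was not covered by it. Gain of chromosome stretches in single tumors may account for the blocks, but the count of 13 of 14 tumors above all shuffles is the pattern itself and adds no support. The 2 chromosomes were picked after their values were seen, all 4 NeuNT tumors had a block on some chromosome, DNA was not measured, and time to tumor stays open.

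Other splits of the same libraries called as many lists as the real groups too often to exclude chance for the counts of lists. Between genotypes 100 of 100 splits reached the real 2 (highest other 17), for MYC-NeuNT tumors against normal glands 24 of 100 reached 16 (highest other 19), and for NeuNT tumors 4 of 35 reached 19 (highest other 19).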
